A study of Mus musculus with 23 samples.

How the data were processed

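The deposited table held 1 column per array, 23 in all, with 22690 probe sets, and no column belonged to no sample. The arrays were Affymetrix MOE430A chips hybridised with RNA from the prefrontal cortex of male C57BL/6 mice, and each array was taken as an independent animal, as titled. Week 5 animal number 2 occurs in both batches, and the labels do not say whether these are different animals; they were counted as 2. The values were in log2 units per the labels and the deposited table: per the labels the authors used GCRMA, a method that adjusts the background with probe affinities, normalises the quantiles between arrays and summarises each probe set. The version of GCRMA was not given. The values were used as deposited, with no further normalisation. Scan day, chip lot and chip type came from the scanner's record of each array. Arrays give no counts, so their number limits the precision. The array medians lay between 6.15 and 6.27 on the log2 scale.

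Age and batch came from the sample titles. Batch 2 held 2 week 2 and 2 week 5 animals. For the array of week 2 animal 5 the title gave batch 1 and the description batch 2. The title was followed, and the other reading was among the alternatives. The 7 scan days were numbered in time order. The 2 arrays of scan day 1, week 5 batch 1 animal 2 and week 10 animal 1, were of 1 chip lot and all other arrays of another. Chip lot and scan day 1 therefore cannot be told apart.

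A probe set was tested when its log2 value was at least 4 on at least 4 arrays, which kept 16103 (71.2%) and left out the 64 control probe sets. Gene symbols came from the platform table through Entrez identifiers and were brought up to date with the mouse genome annotation GRCm38. Of the 22690 probe sets, 20393 carried 1 symbol, 691 several and 1606 none, and 20364 of the first were matched by identifier. The tested probe sets covered 9198 genes.

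Differences between ages were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of all 23 arrays with a mean per age and batch as a term. Each p was adjusted by the Benjamini-Hochberg method over all tested probe sets of a comparison, and a probe set was called when its adjusted p was under 0.05. The 5 comparisons were week 10 against week 2 and each sampled age against the one before it. A moderated F-test asked whether a probe set differed among the 5 ages, the batch difference was tested in the same fit, and week 5 was compared with week 2 within each batch. SE denotes the standard error of a fitted log2 change, and SD the spread between animals of a group. The fits with scan day as a random block (limma duplicateCorrelation, correlation 0.323) or as a fixed term, each in place of the batch term unless said otherwise, stand beside the counts they changed. Week 3 shared no scan day with another age, so the fixed term could not be fitted with it.

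The comparisons, the 37 gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. The lists covered cell types of the cortex, vessels, meninges, choroid plexus, blood and neighbouring brain regions, and groups of synaptic, channel, growth, metabolic and other genes. Each gene was represented by the probe set with the highest mean over all arrays, and counts of genes used that probe set alone. Of the lists, 35 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 175 tests of lists and comparisons. Camera with a correlation estimated per list was the alternative. In both forms the test compares a list with all other genes. Counts of members called were taken from the adjustment over all probe sets and, separately, from one over the members of the list.

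The genes to be named were set by the rule as follows, each gene by its representative probe set. For week 10 against week 2 these were the 12 genes that rose and the 12 that fell most among called probe sets with 1 symbol whose animals did not overlap between the ages. For the other comparisons the numbers were 5 and 5, or fewer where fewer were called. From each list came up to 4 called members with the largest change in week 10 against week 2, or the 2 with the highest mean where none was called. A gene named outside the rule is said to be so.

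RNA integrity was followed by the log2 difference between the 3 prime and 5 prime probe sets of the beta-actin and Gapdh controls, and the range of its group means was tested by permutation. Alternatives of the first set covered the batch term, the label of week 2 animal 5, scan day as a block, normalisation, the filter, the limma settings, array weights, the animal number as a block, the fold threshold, leaving out each array in turn, and the list test. The alternatives without week 3, without scan day 1, with scan days 6 and 7 as 1 term in place of batch, with the actin difference as a covariate and with scan day as a fixed term without week 3 were added after the data were seen, as were scan day as a random block for the lists and the timing and scan day as a random block beside the batch term.

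The procedure was tested on simulated data with the measured spread of 16103 probe sets. For week 10 against week 2 it recovered 34 of 67 simulated changes of 0.5, 63 of 67 changes of 1 and 64 of 66 changes of 2 on the log2 scale, and called 16 unchanged probe sets. No list was called among 175 list tests with no simulated change. The simulated probe sets varied independently, so this run cannot show how the list test behaves where members of a list vary together. In the measured data the median correlation between members within ages ran from -0.04 (channel list) to 0.66 (myelin) and 0.78 (striatal).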

Results

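RNA from the prefrontal cortex of male C57BL/6 mice was measured on 23 arrays at postnatal weeks 2, 3, 4, 5 and 10, with 6, 4, 4, 5 and 4 animals. The series asks how gene expression changes as the cortex matures after birth. Batch 2 held 2 animals of week 2 and 2 of week 5, and the other 19 animals were in batch 1. The arrays were scanned on 7 days, and age and scan day were largely confounded. All 4 week 3 arrays were scanned on day 6, which held no other age. All 4 week 4 arrays were scanned on day 5, with 1 array of week 5. The 2 batch 2 arrays of week 2 and 1 batch 2 array of week 5 were scanned on day 7. Weeks 2 and 10 met on day 4, with 1 array each. The first principal component held 31.5% of the variance, and 90.8% of it lay between scan days against 67.1% between ages. More groups take up more variance by construction, and there were 7 days against 5 ages. Its correlation with the actin 3 prime minus 5 prime difference was 0.855 in size. The actin 3 prime minus 5 prime difference, a measure of RNA integrity, was 2.07 ± 0.38 (SD, n = 4) at week 4 and 1.28 ± 0.23 (SD, n = 6) at week 2, the lowest mean being 1.18 ± 0.08 (SD, n = 4) at week 3. Its range over the ages was 0.90 (permutation p = 0.00074, adjusted p = 0.00296, 2-sided, 4 relations). The same difference of Gapdh had a range of 0.06 over the ages (permutation p = 0.994). Over the scan days the ranges were 0.93 for actin (adjusted p = 0.0447) and 0.55 for Gapdh (adjusted p = 0.00378).

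Between weeks 2 and 10 the gene that fell most was Col3a1, a fibrillar collagen chain on chromosome 1, from 8.63 ± 0.33 (SD, n = 6) to 5.26 ± 0.37 (SD, n = 4) on the log2 scale. Its fitted change was -3.44 (SE 0.26), 10.8-fold (adjusted p = 1.45e-08). Cd24a, a surface glycoprotein of immature neurons, fell by 3.05 (SE 0.33), 8.28-fold. Marcksl1, an actin-binding relative of MARCKS, fell by 2.52 (SE 0.16), from 12.54 to 10.02. Dnmt3a, a de novo DNA methyltransferase, fell by 2.03 (SE 0.13), 4.08-fold (adjusted p = 1.97e-09). Ppic, a cyclophilin isomerase, fell by 2.87, and Npnt, an integrin-binding matrix protein, by 2.50. Nid1, a nidogen of basement membranes, fell by 2.45, and Dpysl3, a collapsin response mediator protein, by 2.27. Cd93, an endothelial receptor, fell by 2.20. Mkrn3, an imprinted makorin, fell by 2.14, Deaf1, a transcription factor, by 2.13, and Cxadr, an adhesion molecule and virus receptor, by 1.99. Ppic, at 2.23, and Mkrn3, at 3.10, stood below the filter value of 4 at week 10, so the size of their fall is not well measured.

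The gene that rose most from week 2 to week 10 was Il33, an alarmin cytokine on chromosome 19, from 5.64 ± 0.26 (SD, n = 6) to 7.90 ± 0.11 (SD, n = 4). Its fitted change was 2.31 (SE 0.17), 4.96-fold (adjusted p = 8.15e-09). Ndrg1 rose by 2.09 (SE 0.21), 4.27-fold, and Aspa, the aspartoacylase of oligodendrocytes, rose by 1.56 (SE 0.27), 2.95-fold. Neat1, the long noncoding RNA of paraspeckles, rose by 1.93 (SE 0.13), 3.82-fold (adjusted p = 3.23e-09). Igfbp6, a binding protein of insulin-like growth factors, rose by 1.96 (SE 0.26), and Qdpr, a dihydropteridine reductase, rose by 1.27 (SE 0.10). Ifit3, an interferon-induced gene, rose by 1.32, and Pde8a, a cyclic AMP phosphodiesterase, by 1.47. The other 4 of the 12 genes with the largest rise were Plekhb1, Adssl1, Efhd1 and Crebrf, with changes of 1.36 to 1.63.

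**Figure D1:**
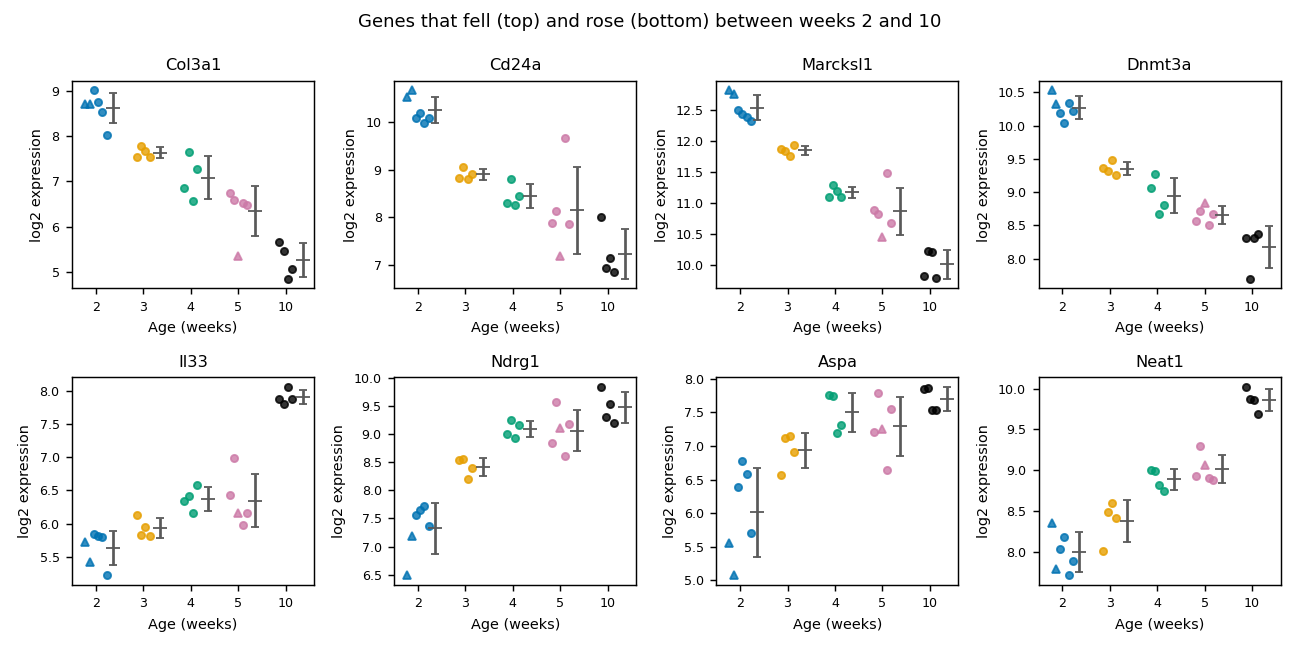
Log2 value of 8 genes in each of the 23 animals by age in weeks. Points are animals, triangles are the arrays of scan day 7, and bars are the mean ± SD. Col3a1, Cd24a, Marcksl1 and Dnmt3a were lower at week 10 than at week 2, and Il33, Ndrg1, Aspa and Neat1 were higher.

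Among the groups, immature neuron genes fell from week 2 to week 10, with 25 of 33 measured genes called lower and 1 higher and a median change of -0.66 (adjusted p = 7.92e-17, limma camera). This call was lost when the inter-gene correlation was estimated (adjusted p = 0.0953 with an estimated correlation). Adjusted over the list alone, 29 fell and 1 rose; Cd24a, Marcksl1, Dpysl3 and Dpysl5 (-1.89) fell most. Extracellular matrix genes fell, 20 of 31 called lower and none higher (22 and 0 adjusted over the list alone), with a median of -0.69 (adjusted p = 2.15e-16), and held with an estimated correlation (adjusted p = 0.0338). Col1a2 fell by 1.76 and Col4a1 by 1.70 beside Col3a1 and Nid1. Oligodendrocyte precursor genes fell, 10 of 13 lower and none higher (11 and 0 adjusted over the list alone), median -0.65 (adjusted p = 8.38e-08), and held with an estimated correlation (adjusted p = 0.0106). Vcan fell by 1.82, Olig2, a transcription factor of the lineage, by 1.09 and Nkx2-2 by 0.78. Perineuronal and neural matrix genes fell, 7 of 10 lower and 1 higher (8 and 1 adjusted over the list alone), median -0.39 (adjusted p = 2.55e-04), but not with an estimated correlation (adjusted p = 0.106 with an estimated correlation). Beside Vcan, Bcan fell by 0.94 and Ncan by 0.86, whereas Hapln2 rose by 1.13.

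Endothelial genes fell, with 9 of 23 called lower and none higher (9 and 0 adjusted over the list alone), median -0.30 (adjusted p = 9.51e-04; adjusted p = 0.144 with an estimated correlation). Slc16a1, a monocarboxylate transporter, fell by 1.90, Vwf by 1.08 and Kdr by 1.02. Pericyte genes fell, 2 of 10 lower and none higher (4 and 0 adjusted over the list alone), median -0.33 (adjusted p = 0.0223; adjusted p = 0.484 with an estimated correlation), with changes of -0.71 for Rgs5 and -0.67 for Notch3. Meninges and fibroblast genes fell, 4 of 11 lower and none higher (4 and 0 adjusted over the list alone), median -0.30 (adjusted p = 0.0155; adjusted p = 0.557 with an estimated correlation). Igf2 fell by 1.64 and Dcn by 1.18. Axon guidance and adhesion genes fell, 11 of 42 lower and 2 higher (12 and 3 adjusted over the list alone), median -0.21 (adjusted p = 0.00756; adjusted p = 0.203 with an estimated correlation), among them Sema5a (-1.18), Cdh13 (-0.96) and L1cam (-0.72). Ketone genes fell, 5 of 11 lower and 1 higher (5 and 2 adjusted over the list alone), median -0.24 (adjusted p = 0.0175; adjusted p = 0.201 with an estimated correlation); Bdh1 fell by 1.13 and Oxct1 by 0.86. Cholesterol synthesis genes fell, 10 of 23 lower and 1 higher (10 and 1 adjusted over the list alone), median -0.27 (adjusted p = 6.10e-04; adjusted p = 0.201 with an estimated correlation), with changes of -1.17 for Tm7sf2, -0.79 for Sqle and -0.61 for Hmgcs1.

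Myelin and mature oligodendrocyte genes rose from week 2 to week 10, with 11 of 27 called higher and 3 lower (11 and 7 adjusted over the list alone), median 0.35 (adjusted p = 0.0126; adjusted p = 0.810 with an estimated correlation). Ndrg1, Aspa and Qdpr rose, while Ugt8a, an enzyme of myelin galactolipids, fell by 1.49. The mean of the list per animal was 8.89 ± 0.34 (SD, n = 6) at week 2 and 9.22 ± 0.12 (SD, n = 4) at week 10 (exact permutation p = 0.105, 2-sided). At week 2 it was 8.51 and 8.46 in the 2 arrays of scan day 7 and 8.87 to 9.26 in the others. The latter overlapped the week 10 animals, which lay at 9.07 to 9.32. Circadian clock genes rose, 3 of 14 higher and none lower (6 and 0 adjusted over the list alone), median 0.31 (adjusted p = 0.0167; adjusted p = 0.484 with an estimated correlation); Dbp rose by 0.99, Bhlhe40 by 0.89 and Nr1d2 by 0.44. Ribosomal protein genes rose, 10 of 40 higher and 3 lower (14 and 3 adjusted over the list alone), median 0.16 (adjusted p = 0.0122; adjusted p = 0.742 with an estimated correlation), although Rplp0 fell by 0.71. The mean of the list per animal was 11.40 ± 0.11 (SD, n = 6) at week 2 and 11.49 ± 0.11 (SD, n = 4) at week 10 (exact permutation p = 0.267, 2-sided). Of 13 groups called in this comparison, 2 were called with an estimated correlation, and all 13 were called with scan day as a random block in place of batch. With scan day as a fixed term the pericyte call was lost (adjusted p = 0.0698).

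The comparison of week 10 with week 2 called 2748 of 16103 probe sets (adjusted p under 0.05, limma, batch as a term), 1031 higher and 1717 lower, in 655 and 1046 genes. Of these, 58 rose and 190 fell at least 2-fold. The excess of falls depended on the scaling of the arrays: with each array centred on its median 1388 were higher and 1340 lower, and after a second quantile normalisation 1473 and 1398. Among all 16103 tested, the 4 and the 6 animals did not overlap in 2368 (14.7%), which chance gives for 0.952%. With scan day as a random block in place of batch 2672 were called, 2313 of them shared; with scan day as a fixed term and no week 3 arrays 1523 were called, 1211 of them shared. On day 4, which held 1 array of each age, 1964 (94.4%) of the 2081 probe sets called without those arrays differed in the called direction.

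**Figure D2:**
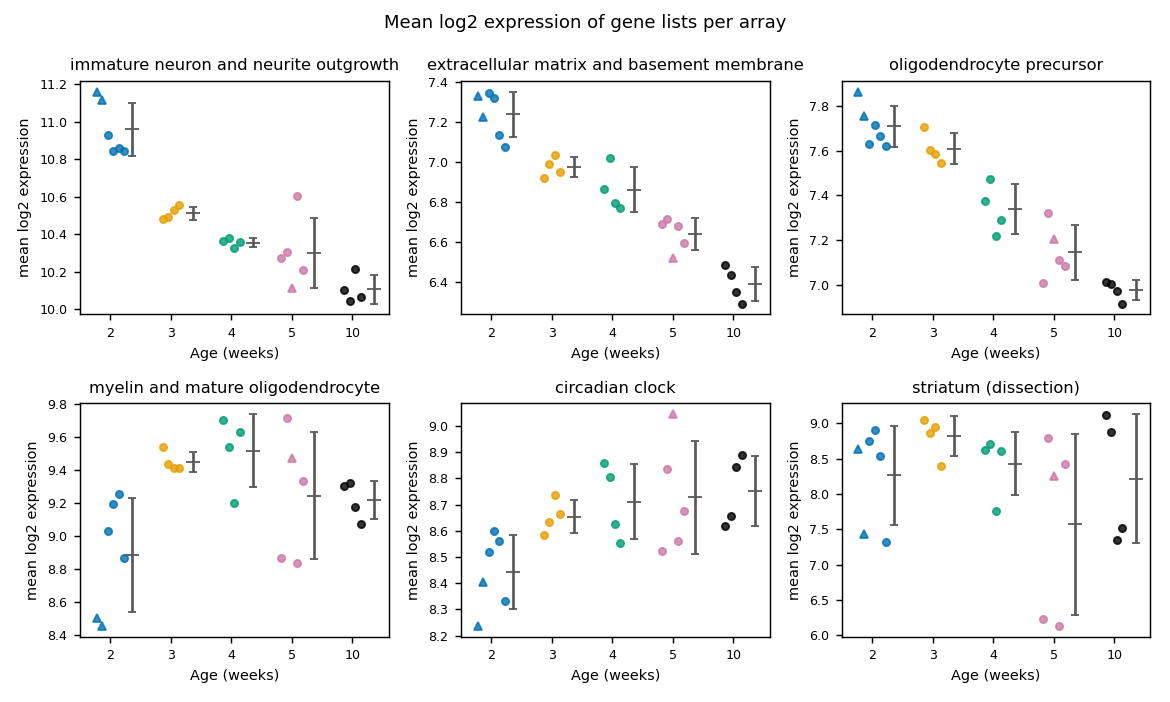
Mean log2 value of 6 gene groups in each of the 23 animals by age in weeks, with triangles for scan day 7 and bars for the mean ± SD. The immature neuron, matrix and oligodendrocyte precursor groups were lower at week 10, while striatal genes varied between animals of 1 age.

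Timing was followed for all 1031 probe sets that rose and 1717 that fell between weeks 2 and 10, as the percent of the whole change reached at an age. The median rising probe set had made 27.5% of its change by week 3, 76.2% by week 4 and 75.1% by week 5. The median falling probe set had made 53.9%, 62.2% and 74.9%. Averaged per animal, the rising share was 30.4% ± 5.69 (SD, n = 4) at week 3 and 74.0% ± 8.33 (SD, n = 4) at week 4, and the falling share was 53.2% ± 3.65 (SD, n = 4) and 60.3% ± 7.81 (SD, n = 4). Il33 departed from these medians: it lay at 6.34 ± 0.40 (SD, n = 5) at week 5, and most of its rise came after that age. With days 6 and 7 as 1 term in place of batch the shares at week 3 were 51.6% rising and 54.5% falling. With batch as the term, among changes of at least 2-fold, the shares at week 3 were 48.5% and 40.1%, so their order turned there. With scan day as a fixed term the falling share at week 4 was 80.2%.

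Between weeks 2 and 3 Kcnc1, a voltage-gated potassium channel, rose by 2.66 (SE 0.35), 6.33-fold (adjusted p = 1.36e-04; n = 4 and 6). Fbxo32, an F-box subunit of a ubiquitin ligase, rose by 2.43, Cnnm1 by 2.35, Tmcc3 by 1.96 and Cygb, a cytoglobin, by 1.94. Sh3d19 fell by 2.13, Mkrn3 by 1.88 (SE 0.27), Ap2b1, a clathrin adaptor, by 1.53, Cxadr by 1.53 and Cd24a by 1.39. Mkrn3 stood at 3.36 at week 3, below the filter value of 4. Fbxo32 stood below it too, at 3.67, in the week 2 arrays of days other than 7, so the size of its rise is not well measured. Of these 10 genes, Kcnc1 (adjusted p = 0.0394), Fbxo32 (adjusted p = 0.0394), Mkrn3 (adjusted p = 0.0128) and Cxadr (adjusted p = 0.0441) stayed called with scan day as a random block in place of batch, and these and Cd24a with days 6 and 7 as 1 term, where the changes of Kcnc1 and Fbxo32 were 0.83 and 0.76. With the block beside the batch term the calls of Ap2b1 and Cd24a were lost. Immature neuron genes fell, 19 of 33 lower and 1 higher (20 and 1 adjusted over the list alone), median -0.39 (adjusted p = 1.25e-07; adjusted p = 0.203 with an estimated correlation), with Dpysl3 at -1.26, Dpysl5 at -1.10 and Marcksl1 at -0.68. Myelin genes rose, 11 of 27 higher and none lower (17 and 0 adjusted over the list alone), median 0.51 (adjusted p = 8.82e-09; adjusted p = 0.484 with an estimated correlation); Ndrg1 rose by 1.04 and Aspa by 0.80. Extracellular matrix genes fell, 9 of 31 lower and 1 higher (10 and 1 adjusted over the list alone), median -0.24 (adjusted p = 0.00628; adjusted p = 0.484 with an estimated correlation), Col3a1 by 1.07 and Nid1 by 0.73, while Col4a1 rose by 0.33.

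Perineuronal and neural matrix genes fell between weeks 2 and 3, with 4 of 10 lower and, adjusted over the list alone, 4 lower and 1 higher (adjusted p = 0.0340; adjusted p = 0.371 with an estimated correlation), among them Vcan at -0.95 and Reln at -0.36. Ketone genes fell, 4 of 11 (adjusted p = 0.0264; adjusted p = 0.203 with an estimated correlation), Slc16a1 by 1.00 and Bdh1 by 0.66. Oxidative phosphorylation genes fell, 11 of 73 lower and 1 higher, median -0.10 (adjusted p = 0.0410; adjusted p = 0.810 with an estimated correlation), Atp5g1 by 0.42. Sodium and potassium channel genes rose, 6 of 26 higher and 1 lower (adjusted p = 0.0135; adjusted p = 0.134 with an estimated correlation), with Kcnc1, Kcnab3 (0.47) and Scn1a (0.42). Striatal genes rose, 2 of 10 called (adjusted p = 0.0139; adjusted p = 0.723 with an estimated correlation), namely Pde10a (1.74) and Meis2 (0.76), both named after their values were seen. These 2 members had the lowest correlations with the rest of the striatal list, 0.592 and 0.641, against 0.758 to 0.983 in the other members, none of which was called. The striatal list mean was 7.32 and 7.43 in week 2 batch 1 animal 6 and batch 2 animal 2. It was 8.54 to 8.90 in the other week 2 animals and 8.40 to 9.05 at week 3. Adjusted over the list alone, the counts of the ketone, oxidative phosphorylation, channel and striatal lists were the same. In all, limma called 2570 probe sets, 1074 higher and 1496 lower, in 518 and 884 genes, 263 and 50 of them by at least 2-fold; with scan day as a random block beside the batch term 337 were higher and 260 lower. Among all tested, the animals did not overlap in 1817 (11.3%), against 0.952% by chance. Scan day as a random block left 112 calls in place of batch and 597 beside the batch term, and with days 6 and 7 as 1 term in place of batch 1158 were called, 631 of them shared. With days 6 and 7 as 1 term the list calls of channels (adjusted p = 0.257), striatal genes (adjusted p = 0.240) and oxidative phosphorylation (adjusted p = 0.261) were lost, the last also with scan day as a random block (adjusted p = 0.0963). That block in place of batch left few called members: 3 immature neuron, 4 ketone and 1 perineuronal and neural matrix gene lower, and 1 channel gene higher. It left none in the extracellular matrix, myelin, striatal and oxidative phosphorylation lists.

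Between weeks 3 and 4 Tmod2, a neuronal tropomodulin, fell by 3.30 (SE 0.46), 9.83-fold (adjusted p = 9.36e-05; n = 4 and 4), and Nr2c2, a nuclear receptor, fell by 3.04. Atp8a1, a phospholipid flippase, fell by 2.88, Fut9, a fucosyltransferase, fell by 2.88 and Zeb2, a transcriptional repressor, fell by 2.85. Prmt1, an arginine methyltransferase, rose by 2.50, Ap2b1 by 2.20, Sh3d19 by 1.54 and Pex5l by 1.23. Gh, growth hormone, was called higher (change 4.93, SE 1.55; adjusted p = 0.0428), but stood below the filter value of 4 at week 3, at 3.41 ± 0.14 (SD, n = 4), and at 8.33 ± 4.86 (SD, n = 4) at week 4. The week 4 value of Gh was 15.48 in animal 2 and 5.18 to 7.31 in the other animals, so the size of its rise rests largely on 1 animal. None of these 10 genes was called with scan day as a random block in place of batch, and Tmod2, Nr2c2, Atp8a1 and Zeb2 were called with it beside the batch term. Tmod2 stood at 11.47 at week 3 and at 8.17 at week 4; it was 11.96 in the scan day 7 arrays of week 2 and 9.42 in the other week 2 arrays. Kcnc1 stood at 9.22 at week 3, 8.16 on the scan day 7 arrays of week 2 and 6.62 at week 4. Of 35 tested groups, limma's camera called 8. Ribosomal protein genes rose, 6 of 40 higher, median 0.16 (adjusted p = 0.00943; adjusted p = 0.742 with an estimated correlation), Rpl37 by 0.39 and Rps19 by 0.35. Immature neuron genes fell, 5 of 33, median -0.11 (adjusted p = 8.84e-04; adjusted p = 0.484 with an estimated correlation), Marcksl1 by 0.67.

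Axon guidance genes fell between weeks 3 and 4, 8 of 42 called (adjusted p = 0.00237; adjusted p = 0.162 with an estimated correlation), L1cam by 0.64. Channel genes fell, 5 of 26 lower and 1 higher (adjusted p = 0.00577; adjusted p = 0.103 with an estimated correlation), Kcnc1 by 2.61 and Kcnip1 by 0.45. Extracellular matrix genes fell, 2 of 31 (adjusted p = 0.00848; adjusted p = 0.490 with an estimated correlation), Col4a1 by 0.89. Oligodendrocyte precursor genes fell, 1 of 13 called, Cspg4 by 1.23 (adjusted p = 0.00122; adjusted p = 0.103 with an estimated correlation). Striatal genes fell, 2 of 10 (adjusted p = 0.0269; adjusted p = 0.742 with an estimated correlation), Pde10a by 2.11 and Meis2 by 0.87. Layer-specific projection neuron genes moved, on balance, down (adjusted p = 0.0461; adjusted p = 0.203 with an estimated correlation), with Rorb at -2.25 and Foxp2 at -1.09 lower and Lamp5 (0.51) and Lmo4 (0.53) higher. Cspg4, Pde10a, Meis2, Rorb, Foxp2, Lamp5 and Lmo4 were named after their values were seen. Pde10a and Meis2 had the lowest correlations with the rest of the striatal list. Adjusted over the list alone, 6 channel genes fell and 1 rose, 3 layer genes fell and 2 rose, and the counts of the other 6 lists were the same. In all, limma called 1839 probe sets, 784 higher and 1055 lower, in 503 and 392 genes, 21 and 444 by at least 2-fold. The larger direction turned with each array centred on its median (1440 higher, 948 lower) and with array weights (2151 and 1527). Among all tested, the animals did not overlap in 3096 (19.2%), against 2.86% by chance. The actin difference was 1.18 at week 3 and 2.07 at week 4. With it as a covariate limma called 0 (1457 at an unadjusted p under 0.05), as the median size of change went from 0.60 to 0.36 and its SE from 0.145 to 0.232. As a random block scan day left 1 call in place of batch and 191 beside the batch term, with days 6 and 7 as 1 term 2 were called, and without week 4 animal 2 1219. With days 6 and 7 as 1 term the list calls of immature neurons (adjusted p = 0.0887), channels (adjusted p = 0.132), axon guidance (adjusted p = 0.187), striatal genes (adjusted p = 0.189) and layer neurons (adjusted p = 0.363) were lost, the last also with scan day as a random block (adjusted p = 0.0877). That block in place of batch left no called member in any of the 8 lists.

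**Figure D3:**
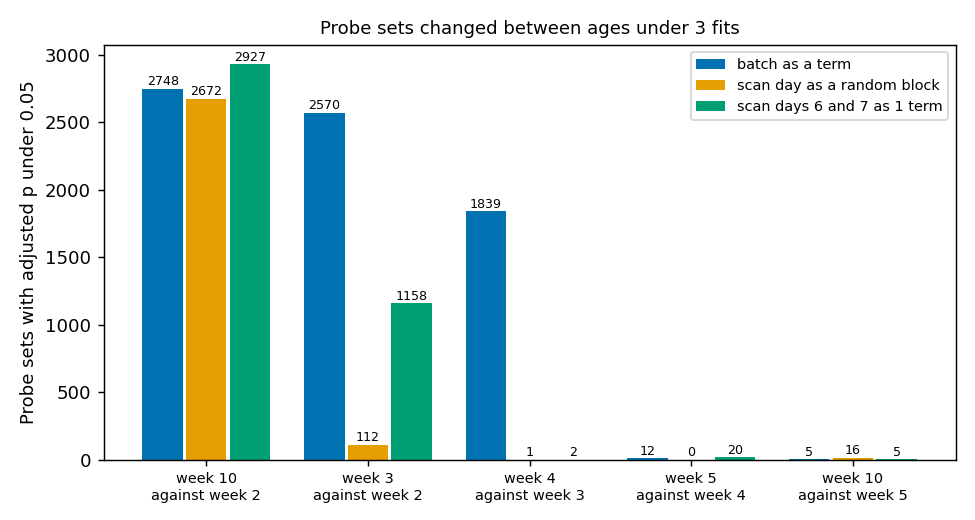
Number of probe sets called in the 5 comparisons under 3 fits: batch as a term, and in place of it scan day as a random block or scan days 6 and 7 as 1 term. Week 10 against week 2 gave 2748, 2672 and 2927 calls, and week 4 against week 3 gave 1839, 1 and 2.

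Week 3 departed from both neighbours in many genes: 888 probe sets were called in both week 3 against week 2 and week 4 against week 3, and 854 of them moved in opposite directions. Both comparisons hold the same 4 week 3 arrays, which alone favours opposite directions: the changes correlated at -0.577 across probe sets, and at -0.529 in simulated groups with no change. The covariance of the changes was -0.0819, against -0.0150 in the simulated groups, where no probe set was called in both. With 2 week 3 animals in each comparison, 309 to 412 were called in both and 302 to 396 moved in opposite directions. Independent lists of those sizes would share 59.8 to 114, and the changes correlated at -0.517 to -0.379. Of the 854, 611 rose and then fell and 243 fell and then rose, among them Kcnc1 and Pde10a, up then down, and Ap2b1 and Sh3d19, down then up. The mean of the 854 in each array, signed by their direction, was -3.67 on the log2 scale over the 4 week 3 arrays, -3.56 over the 3 arrays of scan day 7, of weeks 2 and 5, and -2.75 over the other 16.

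**Figure D4:**
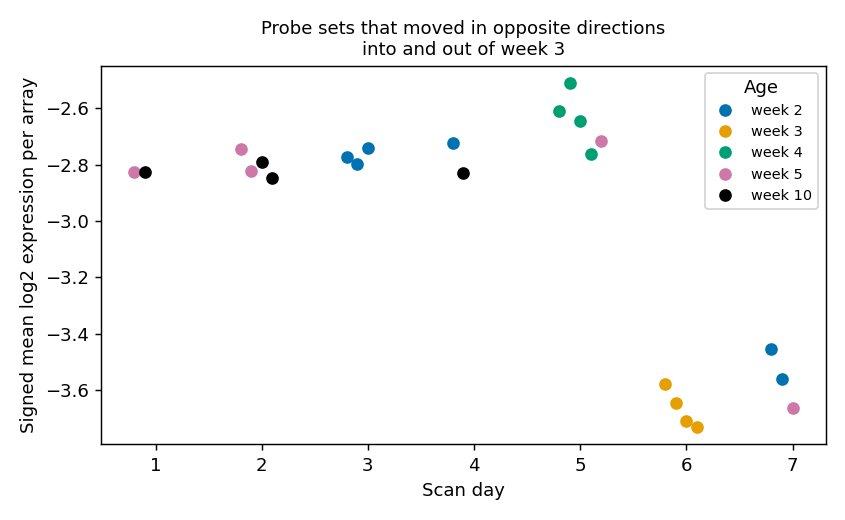
Signed mean log2 value of the 854 probe sets that moved in opposite directions before and after week 3, for each of the 23 arrays by scan day and coloured by age. The arrays of scan day 7, of weeks 2 and 5, lay between -3.67 and -3.46, and the week 3 arrays between -3.73 and -3.58.

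Between weeks 4 and 5 limma called 12 probe sets (2100 at an unadjusted p under 0.05), 3 higher and 9 lower, in 1 and 6 genes; with days 6 and 7 as 1 term 14 were higher and 6 lower. By the naming rule Tmem242, a transmembrane protein, rose by 0.75 (SE 0.13; adjusted p = 0.0277). A probe set of Gfap, the astrocyte filament protein, fell by 0.76 (adjusted p = 0.00858), one of Fmnl1, a formin, by 1.04 (adjusted p = 0.00618), and Col4a1, a basement membrane collagen, by 0.64 (adjusted p = 0.0314); Gfap and Fmnl1 were named after their values were seen. Extracellular matrix genes fell, 1 of 31 (5 adjusted over the list alone), median -0.21 (adjusted p = 0.00237; adjusted p = 0.461 with an estimated correlation). Pericyte genes fell, none called and 3 of 10 adjusted over the list alone, median -0.33 (adjusted p = 0.00848; adjusted p = 0.388 with an estimated correlation), and precursor genes fell, none called and 4 of 13 adjusted over the list alone (adjusted p = 0.00577; adjusted p = 0.143 with an estimated correlation). Myelin genes fell with a median of -0.19 (adjusted p = 0.0486; adjusted p = 0.852 with an estimated correlation) and striatal genes with -1.12 (adjusted p = 0.00577; adjusted p = 0.648 with an estimated correlation), and channel genes rose (median 0.02, adjusted p = 0.0451; adjusted p = 0.203 with an estimated correlation); in these 3 lists no member was called, nor adjusted over the list alone. The striatal list mean was 6.23 and 6.13 in week 5 batch 1 animals 2 and 7 and 8.26 to 8.80 in the other 3 week 5 animals. With scan day as a random block in place of batch the list calls of precursor (adjusted p = 0.0924), striatal (adjusted p = 0.504) and myelin genes (adjusted p = 0.904) were lost. With scan day as a fixed term those of precursor (adjusted p = 0.943), pericyte (adjusted p = 0.184), striatal (adjusted p = 0.161) and channel genes (adjusted p = 0.0898) were lost. Among all tested, the animals did not overlap in 532 (3.30%), against 1.59% by chance. No probe set was called by limma with scan day as a random block in place of batch (1095 at an unadjusted p under 0.05) or beside it (1058). Without week 4 animal 6 the count was 303, without week 5 batch 2 animal 2 it was 106, without week 5 batch 2 animal 4 it was 50, and without week 10 animal 1 it was 21. Without any 1 of week 4 animals 1, 2 and 3 or of week 5 batch 1 animals 2, 7 and 8 it was 2 to 4.

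Between weeks 5 and 10 Il33 rose by 1.61 (SE 0.17), 3.06-fold (adjusted p = 1.40e-04; n = 4 and 5), and Neat1 rose by 0.92 (SE 0.14), 1.90-fold (adjusted p = 0.00572). Capn5, a calpain, fell by 1.00 (SE 0.15; adjusted p = 0.00823). The other calls were a second probe set of Marcksl1 (-0.78, adjusted p = 0.00362) and Tnnc1, a troponin C (-1.45, adjusted p = 0.0231), both named after their values were seen. Ribosomal protein genes rose, median 0.16 (adjusted p = 1.26e-12; adjusted p = 0.203 with an estimated correlation), striatal genes rose, median 0.80 and 1 of 10 adjusted over the list alone (adjusted p = 6.41e-05; adjusted p = 0.484 with an estimated correlation), and immediate early genes rose, median 0.16 (adjusted p = 0.0261; adjusted p = 0.742 with an estimated correlation). Without week 5 batch 1 animal 2 the immediate early median was -0.05 (adjusted p = 0.995). The striatal list mean was 6.23 and 6.13 in week 5 batch 1 animals 2 and 7, 8.26 to 8.80 in the other week 5 animals and 7.35 to 9.12 at week 10. Extracellular matrix genes fell, median -0.16 and 6 of 31 adjusted over the list alone (adjusted p = 4.25e-09; adjusted p = 0.115 with an estimated correlation). Immature neuron genes fell, median -0.11, with 2 lower and 1 higher adjusted over the list alone (adjusted p = 5.63e-04; adjusted p = 0.484 with an estimated correlation).

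Endothelial genes fell between weeks 5 and 10, median -0.11 and 1 of 23 adjusted over the list alone (adjusted p = 0.00756; adjusted p = 0.203 with an estimated correlation), as did meninges genes, median -0.21 (adjusted p = 0.0122; adjusted p = 0.517 with an estimated correlation). Ketone genes fell, median -0.08 and 1 of 11 adjusted over the list alone (adjusted p = 0.0203; adjusted p = 0.203 with an estimated correlation), postsynaptic density genes fell, median -0.06 (adjusted p = 0.0264; adjusted p = 0.484 with an estimated correlation), and glycolysis genes fell, median -0.08 (adjusted p = 0.0477; adjusted p = 0.691 with an estimated correlation). No member of the 10 lists called in this comparison was called over all probe sets, nor, in those given no such count, adjusted over the list alone. The comparison called 5 probe sets (877 at an unadjusted p under 0.05), 2 higher and 3 lower. With only the arrays of these 2 ages limma called 0 (708 at an unadjusted p under 0.05), and without the scan day 1 arrays it called 1. Among all tested, the animals did not overlap in 251 (1.56%), against 1.59% by chance. A random block of scan day in place of batch gave 16 calls, 4 of them shared, and the list calls of glycolysis (adjusted p = 0.195) and immediate early genes (adjusted p = 0.312) were lost with it. A fixed term of scan day lost these (adjusted p = 0.186 and 0.125) and the meninges list (adjusted p = 0.0552). The count was 9 without week 5 batch 2 animal 2 or without week 5 batch 1 animal 8, and 3 without week 5 batch 1 animal 7 or week 10 animal 7.

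The F-test across the 5 ages, which asked for any difference among them, called 5085 of 16103 probe sets (31.6%), in 2848 genes, Col3a1, Il33, Marcksl1 and Neat1 among them. It called 1811 with scan day as a random block in place of batch, of which 1799 were shared. Of the 5085, 824 were called in none of the 5 comparisons.

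Weeks 2 and 5 were the ages that both batches held. Over all 23 arrays limma called 2429 probe sets in week 5 against week 2 (921 higher, 1508 lower), 1809 with scan day as a random block in place of batch and 1033 as a fixed term. With the arrays of batch 1 alone 792 were called, and with those of batch 2, 2 against 2, none were called by limma (2982 at an unadjusted p under 0.05). Of the 792, 668 (84.3%) changed in the same direction in batch 2; across probe sets, which are not independent replicates, the changes in the batches correlated at 0.408. The interaction of age and batch was called in 33 probe sets, among them Igfbp6, whose change was 1.83 in batch 1 and 3.57 in batch 2 (adjusted p = 0.0349), and Efhd1, with 0.78 and 2.28 (adjusted p = 0.00978). The batch term was called in 822 probe sets, 628 higher and 194 lower in batch 2. Without 1 array of batch 2 it was called in 171 (week 5 animal 4), 318 (week 2 animal 1), 340 (week 2 animal 2) or 1794 (week 5 animal 2), and with week 2 animal 5 in batch 2 limma called 0 (2103 at an unadjusted p under 0.05). On day 7, 1271 (82.4%) of the 1542 probe sets called in week 5 against week 2 without that day's arrays differed in the called direction.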

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

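The tests of RNA integrity in the step from week 2 and without scan day 7 and of dissection for the striatal genes were chosen only after the result was seen, as was the fit with scan days 6 and 7 as 1 term.

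In 390 groups of 4 to 6 animals tested for 1 animal far from the others (41 genes, 35 gene groups and 2 RNA controls at the 5 ages), 18 held one, where chance gives about 1 in 20 groups, or 19.5. Of these, 5 fell on week 5 batch 2 animal 4, the only week 5 array of scan day 7. In it Kcnc1 was at 9.54 (6.81 to 7.27 in the other 4 animals), Fbxo32 at 6.23 (3.53 to 3.85), Cnnm1 at 8.62 (5.87 to 6.07), Col3a1 at 5.36 (6.49 to 6.73) and the meninges list mean at 6.10 (6.47 to 6.59). Prmt1 was at 7.85 in week 2 batch 2 animal 2, also of day 7, against 9.33 to 9.79 in the others.

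The remaining far animals were as follows. In week 10 animal 6 Dnmt3a was at 7.70 (8.31 to 8.38 in the others) and the DNA methylation and chromatin mean at 8.47 (8.58 to 8.60). In week 10 animal 1 Cxadr was at 5.92 (6.29 to 6.34), the sodium and potassium channel mean at 7.95 (8.14 to 8.16) and the chaperone mean at 10.82 (10.60 to 10.61). In week 10 animal 8 the astrocyte mean was 9.94 (10.08 to 10.09). In week 3, Cygb was at 9.01 in animal 3 (9.25 to 9.28), the myelin mean at 9.54 in animal 2 (9.41 to 9.44) and the presynaptic mean at 10.24 in animal 5 (10.18 to 10.19). In week 4 the striatal mean was 7.76 in animal 3 (8.61 to 8.71) and the actin difference 1.50 in animal 6 (2.25 to 2.28). In week 5 batch 2 animal 2 the olfactory bulb mean was 6.73 (5.32 to 5.58). The change from week 2 to week 5 differed between batches, by a limma interaction test adjusted over all probe sets and read for 147 named genes, for Igfbp6 by 1.74 (adjusted p = 0.0349) and for Efhd1 by 1.50 (adjusted p = 0.00978).

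The first pattern is the departure of week 3 from both neighbours in 854 probe sets, whose signed mean in the 3 arrays of scan day 7 (-3.56) lay near that of week 3 (-3.67) and not near that of the other 16 arrays (-2.75). Arrays of 1 age differed between scan days in this score by up to 0.950 in week 5 (1 array of day 7), 0.784 in week 2 and 0.0131 in week 10, the largest being 1.12 times the departure of week 3, so scan day may account for it; with days 6 and 7 as 1 term, 2 probe sets were called between weeks 3 and 4. The actin difference predicted the direction of 95.9% of the 854 in week 4 against week 3 from the slopes within weeks 2, 5 and 10 (93.0% to 97.0% without 1 array), against 72% over all probe sets, but of 47.0% without the arrays of day 7, on which those slopes rest; as the 12 arrays left had actin differences of 1.27 to 1.78 and week 3 had 1.07 to 1.24, it cannot be told whether RNA integrity accounts for the step to week 4. With the actin difference as a covariate, 84.8% of the 854 were still called in week 3 against week 2. The change it predicted there (median 0.13 of the observed change) rests on the same slopes, so that prediction settles nothing about the step. Age was tested no further, since all week 3 arrays and no others were scanned on day 6, and week 3 and day 6 cannot be told apart.

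The second pattern is the spread of striatal markers between animals of 1 age. The mean of the 10 listed genes ran from 6.13 to 9.12 over the 23 arrays, with a range of 2.67 within week 5. Between the age means these genes had a range of 1.25 (permutation p = 0.157). Their residuals moved together, with a median pairwise correlation of 0.782 against at most 0.520 in 953 matched random lists, so a varying share of striatum in the dissected tissue is a candidate explanation; Penk ran from 8.33 to 12.2, Tac1 from 8.27 to 11.6 and Ppp1r1b from 6.63 to 10.7, genes that cortex also expresses. RNA integrity is argued against, as the residual list mean was unrelated to the actin difference (r = -0.0123, permutation p = 0.956; rho = 0.0889, p = 0.728; r = 0.0928 without the 2 farthest arrays). Regulation of the same genes within the cortex stays open and untested.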

How the results depend on the processing

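The fits without week 3 or scan day 1, with days 6 and 7 as 1 term, with the actin covariate, with a fixed scan day term, with scan day as a random block beside batch, and with it in place of batch for lists and timing were chosen after seeing the data. For week 10 against week 2, 77 of 122 genes and 2 of 13 lists called kept their call and direction under every alternative run for them. The numbers were 4 of 10 and 0 of 8 for week 3 against week 2, 0 of 10 and 0 of 8 for week 4 against week 3, 0 of 1 and 0 of 6 for week 5 against week 4, and 0 of 3 and 0 of 10 for week 10 against week 5. No named gene reversed. Probe sets near background limit what the arrays can show. Animal numbers did not pair the samples: the closest array of another age shared the number in 1 of 23 arrays and the scan day in 7.

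Where a value below changed, the cause was not tested, except that a fold threshold leaves fewer calls by construction. With scan day as a random block in place of batch the 5 ages gave 1811, week 3 against 2 112, week 4 against 3 1, week 5 against 4 0 (1095 at an unadjusted p under 0.05, limma) and week 10 against 5 16. Beside the batch term it gave 2199, 597, 191 and 0 (1058 unadjusted) for the 5 ages and the steps to weeks 3, 4 and 5. With a fixed scan day term week 10 against 2 gave 1523, week 5 against 4 0 (714 unadjusted), and the falling share at week 4 was 80.15%. With days 6 and 7 as 1 term the counts were 3260 (5 ages), 1158 (week 3 against 2), 2 (week 4 against 3) and 20 (week 5 against 4), and the rising share at week 3 was 51.61%. With the actin covariate week 4 against 3 gave 0 (1457 unadjusted), week 5 against 4 0 (1170 unadjusted) and week 10 against 5 9. Without week 3 the F-test, then over the remaining ages only, gave 2635, and week 5 against 4 gave 2. Without scan day 1 week 10 against 5 gave 1. At 1.5-fold the counts were 2556 (5 ages), 993 (week 10 against 2), 966 (week 3 against 2) and 949 (week 4 against 3). Array weights gave 4212, 3678 and 835 for the steps to weeks 3, 4 and 5. The replicate block gave 3345 (5 ages), 3 (week 5 against 4) and 2 (week 10 against 5).

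Week 5 against 4 also gave 6 with no batch term, 369 with batch 1 only, 3 with batch as a random block, 2 with week 2 animal 5 in batch 2 and 0 with only those 2 ages (2520 unadjusted). Week 10 against 5 gave 0 with only those ages (708 unadjusted). The batch difference gave 0 with week 2 animal 5 in batch 2 (2103 unadjusted) and 0 with only weeks 2 and 5 (2765 unadjusted). With an estimated correlation 2 list tests were called. Among changes of at least 2-fold the share at week 3 was 48.47% rising and 40.06% falling. The immediate early list at week 5 against 4 was 0.1176 with scan day as a random block, and the myelin list at week 10 against 5 was -0.1611 without scan day 1; both had turned direction. Leaving out 1 array at a time gave ranges of 1219 (without week 4 animal 2) to 2115 for week 4 against 3, 2 (week 4 animal 1) to 303 (week 4 animal 6) for week 5 against 4, 3 to 9 for week 10 against 5, 171 (week 5 batch 2 animal 4) to 1794 (week 5 batch 2 animal 2) for batch and 48.32% to 57.51% for the falling share at week 3. For lists that turned it gave -0.08627 (week 5 batch 1 animal 7) to 0.02522 for immature neurons in week 5 against 4, and in week 10 against 5 -0.1211 (week 5 batch 1 animal 2) to 0.08415 for myelin and -0.04591 (the same animal) to 0.365 for immediate early genes.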

Other observations

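The test of chance for the lists of week 10 against week 2, the exact tests per list and the tests of scan day, RNA integrity and vessel wall cells for the genes changed between weeks 2 and 10 were chosen after the result was seen.

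Among gene groups not called from week 2 to week 10 by limma's camera, single members still changed. Pvalb rose by 1.27, Gad1 by 0.63, and Reln fell by 0.53 among 22 interneuron genes (2 higher, 2 lower, median -0.02, adjusted p = 0.799). Of 23 astrocyte genes 3 rose and 6 fell (median -0.11, adjusted p = 0.437), with Fabp7, the fatty acid binding protein of radial glia, at -1.63 and Gfap at -0.88 against S100b at 0.50. Of 19 microglia genes 2 rose and 3 fell (median 0.07, mean -0.03, adjusted p = 0.549), with Mrc1 at -1.17, Tmem119 at -0.80 and Ctss at 0.66. Of 29 presynaptic genes 4 rose and 4 fell (6 and 10 adjusted over the list alone; median -0.26, adjusted p = 0.439); Vamp1 rose by 0.85 and Snap25 by 0.55. Of 21 postsynaptic density genes 6 fell (median -0.25, adjusted p = 0.103), Dlg4, a scaffold protein of excitatory synapses, by 1.27. Of 26 sodium and potassium channel genes 4 rose and 1 fell (median 0.02, adjusted p = 0.225), and of 30 DNA methylation and chromatin genes 4 rose and 6 fell (median -0.11, adjusted p = 0.431), Dnmt3a and Ezh2 (-0.67) lower and Ezh1 (0.78) higher. Of 26 growth factor genes 1 rose and 8 fell (median -0.06, adjusted p = 0.260), Igf1 by 1.28.

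Of 10 antigen presentation and interferon genes 3 rose (median 0.18, adjusted p = 0.0554), Ifit3, B2m and H2-D1. Of 18 cell cycle genes 3 fell, Rrm2 by 1.93 (median 0.03, mean -0.15, adjusted p = 0.63). For the other lists the members that rose and fell, median and adjusted p were 1 and 3 of 22, -0.10 and 0.394 for layer projection neurons, 0 and 2 of 11, -0.04 and 0.546 for glutamate receptors, 0 and 1 of 17, -0.12 and 0.731 for monoamine signalling, 3 and 2 of 15, 0.05 and 0.553 for chloride and ion homeostasis, and 4 and 3 of 16, 0.14 and 0.459 for glycolysis. They were 4 and 11 of 73, -0.08 and 0.136 for oxidative phosphorylation, 3 and 7 of 35, 0.00 (mean -0.07) and 0.617 for chaperones, and 0 and 2 of 14, -0.02 and 0.396 for glucocorticoid response. No member was called by limma among 6 olfactory bulb (median -0.27, adjusted p = 0.464), 10 striatal (0.14, 0.648), 17 immediate early (0.15, 0.549) and 6 GABA-A receptor genes (0.04, 0.876). Adjusted over the list alone the members that rose and fell were 4 and 7 for astrocytes, 2 and 3 for interneurons, 0 and 7 for the postsynaptic density, 2 and 8 for growth factors, 4 and 7 for DNA methylation, 4 and 12 for oxidative phosphorylation and 3 and 8 for chaperones; beside these and the presynaptic list the counts were the same. The median differed in sign from the mean or the test for cell cycle, microglia and chaperones here and for lists not called in the other comparisons, such as astrocytes and axon guidance at week 3, the perineuronal and neural matrix list and myelin at week 4, immature neurons and interneurons at week 5 and myelin and microglia at week 10. The choroid plexus and blood cell lists had too few measured members to test: Ttr averaged 4.76 with a maximum of 7.20, and Alas2 averaged 6.26 and Hbb-b2 6.85. The blood genes Alas2, Hbb-b2, Slc4a1 and S100a9 had their highest means at week 3 (7.49, 7.29, 6.37 and 4.56). At week 2 they stood at 6.26, 6.80, 5.72 and 4.21, and Alas2 was at 5.26 at week 10. In exact tests of list means per animal, added after the data were seen, 17 of 35 lists differed between weeks 2 and 10 at an adjusted p under 0.05 (2 higher, 15 lower), 11 of them called by camera; 0.00476 is the smallest p that 210 splits can give.

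The third pattern is the set of 2748 probe sets that differed between weeks 2 and 10. Scan day is argued against as the whole cause: with scan day as a fixed term 44.1% of the 2748 were still called, with a median change in the called direction of 0.49 before and after while the median SE went from 0.117 to 0.157; in the 1 animal of each age scanned on day 4, 94.4% of the probe sets called without them differed in the called direction. RNA integrity as tracked by the actin difference is argued against as the whole cause too, since 83.0% of the 2748 were still called with it as a covariate. The Gapdh difference, 0.75 in week 10 animal 1 and 0.02 to 0.15 in the other week 10 animals, was not used as a covariate. A smaller share of vessel wall cells would lower the matrix and endothelial lists alike if both were equally specific to those cells. The mean of the matrix list minus that of the endothelial list fell by 0.484 on the log2 scale (exact permutation p = 0.00476, adjusted p = 0.00667). This argues against such an equal fall, but how specific the lists are was not tested, so a smaller share is not excluded. Pericyte and meninges list means fell by 0.325 and by 0.382, and with shared genes left out the matrix list fell further than either, its difference from them being -0.53 and -0.53 (each exact permutation p = 0.00476); a change within the cells that make matrix, and age itself, stay open and untested.

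In other splits of the same samples into groups of the same sizes, chance can be excluded for week 10 against week 2 (2748 probe sets, 1 of 100 splits, highest other 559), week 3 against week 2 (2570, 1 of 100, 67), week 4 against week 3 (1839, 1 of 35, 0), the 5 ages (5085, 1 of 100, 58) and week 5 against week 2 in batch 1 (792, 1 of 35, 50). In week 3 against week 2, week 4 against week 3 and week 5 against week 2 in batch 1, the ages shared no scan day. The splits therefore do not set age apart from scan day in these comparisons. Where there were 35 splits, 1 is also the lowest count that the test can give. All of these splits treat the arrays as exchangeable, which a likeness of arrays within scan days would break. The exclusion of chance holds under that condition only. Of 100 splits, 3 gave as many list calls as week 10 against week 2 did (13, highest other 14), the real split among them. This test of 1 comparison was chosen after the result was seen, so it is no firm ground to exclude chance for the lists. For the batch difference 3 of 100 splits gave as many calls (822, highest other 1117), but the highest followed scan day 7, so these splits do not set batch apart from the scan days. Chance cannot be excluded for week 5 against week 4 (12, 12 of 100, 434), week 10 against week 5 (5, 10 of 100, 751) and the lists over all comparisons (45, 7 of 100, 52). The split with 434 calls set 4 arrays of scan day 5 against 1 other of that day and 4 of days 1, 2 and 7, and that with 751 set days 1, 5 and 7 against days 2 and 4; with scan day as a random block those comparisons gave 0 and 16 calls. The split with 1117 calls joined the 3 arrays of scan day 7 with 1 array of scan day 1. The counts of 751 and 1117 point to a structure of the samples that follows the scan days. The count of 434 does not, as the real split of week 5 against week 4, with 12 calls, held the same scan days. The split with 434 calls exchanged week 4 animal 6 and week 5 batch 2 animal 2, both scanned on day 5. Without week 4 animal 6 the real split gave 303 calls.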
